A study of Arabidopsis thaliana with 24 samples.

How the data were processed

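The series held 2 processed tables for the same 24 libraries, read counts per gene and FPKM per gene, in units stated by the file headers and the authors' processing notes. The count table listed 32833 genes, of which 28056 had any count, and the FPKM table listed 28056 genes. Per the deposited count table, the values were whole read counts per gene, and these were used for all main tests. Per the deposited FPKM table, the values were fragments per kilobase and sequencing depth, and these were used only in 1 alternative. The submitters' processing notes name HISAT2 2.0.4, HTSeq 0.6.1p1 and TAIR10. The strand setting of the read counting was not given in the sources used here. Raw reads were not used here.

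Gene identifiers were matched to the TAIR10.1 annotation, which 32548 loci fitted, and 10913 of these had a symbol. Libraries held 17600922 to 21557382 assigned reads. No library was left out.

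Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with DESeq2 1.42.0 as an alternative and Python 3.11.15 for preparation and figures. Counts were scaled by TMM, genes with low counts were removed by filterByExpr, and a robust quasi-likelihood model was fitted to the 12 libraries of the salt set, of the heat set, and of the 2 unstressed conditions. Each fit had 8 residual degrees of freedom. This left 21759, 21196 and 21529 genes. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Interactions were tested as the difference between genotypes in the response to a condition.

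For gene lists, 27 were tested, 25 of them written by hand from general knowledge before the data were examined. Of 460 members 434 were matched to a tested locus name, and 26, many of them small heat shock protein genes, were left out. Lists were tested by limma's camera with a preset correlation of 0.01 and again with the correlation estimated per list, and p-values were adjusted over lists. Counts of members that changed were also made after adjusting over the list alone.

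Genes were named by a rule fixed beforehand. EXA1 was given for every library with its neighbours on the chromosome. CPM of EXA1 and its neighbours were scaled to the library total, and all other CPM to totals adjusted by TMM. In each comparison the 5 largest rises and 5 largest falls were eligible if they had a symbol, an adjusted p below the threshold, at least 5 CPM in the higher group and no overlap between replicates of the groups. Up to 4 members per list and marker genes of salt, heat and defence chosen in advance completed the names. Of the genes that this rule gave, 1 is not reported here. Sugar-starvation genes, clock phases and the comparison of genotype differences between the 2 unstressed groups were added after the data were seen or with a prediction written before the test, as stated with each.

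Alternatives were DESeq2, limma-trend on log2(FPKM + 1), RLE size factors, no filter on low counts, all 24 libraries in 1 fit, only the 6 libraries compared, replicate number as a block, organelle genes left out, and each library left out in turn. Chance was assessed by regrouping libraries, 10 splits for 3 against 3 and 60 for interactions. Response sizes were compared by total least squares, overlaps by Fisher's exact test, and medians by 2000 bootstrap draws with a 95% interval. The draws were over genes of a list, so the intervals do not measure the spread between libraries. Folds against a group without reads were given as a lower bound, with 3 counts over the group as the floor.

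The test was checked on simulated counts drawn with the mean and dispersion of each gene, in which 200 genes were changed by known amounts. Each gene had 1 mean over the 12 libraries of a fit, so no response to salt or heat was simulated. At log2 changes of 0.5, 1 and 2, the share recovered was 79.1, 91 and 98.5% on MS (4.8% of calls false), and 49.3, 74.6 and 87.9% at 23 °C (7.2% false). It was 56.7, 86.6 and 93.9% for the interaction with salt (5.4% false) and 16.4, 67.2 and 87.9% for the interaction with heat (7.3% false). In the simulation a heat interaction of log2 = 0.5 was therefore mostly missed.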

Results

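Arabidopsis seedlings of the wild type and of the exa1-1 mutant were sequenced in 2 sets, each with its own unstressed group. The salt set held seedlings on control medium (MS) and with 200 mM NaCl, and the heat set held seedlings at 23 and 39 °C, with treatments of 60 min. Each of the 8 groups had 3 libraries, 24 in all, with 17600922 to 21557382 assigned reads per library. The series text gives 3 independent biological replicates but does not state how the cultures were kept separate, so p-values measure the spread between these samples. EXA1 encodes a GYF-domain protein that has been linked to repression of translation and to the control of immune receptors. Expression was compared between genotypes within each condition and between conditions within each genotype. Whether the response to salt or to heat differed between genotypes was tested as an interaction, and the 2 unstressed groups were also compared. The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined, except where stated. Floors given with fold changes cover counting error only. Standard errors were obtained as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. They are approximate and can be too small where a group has few reads. The standard error of an interaction therefore need not follow from those of its 2 responses.

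EXA1 (AT5G42950) transcript was reduced in every mutant library. Wild-type libraries held 1488 to 3111 EXA1 reads and exa1 libraries 143 to 342. In counts scaled to the library total (CPM; mean ± SD, n = 3 per group), EXA1 was 93.4 ± 0.718 in the wild type and 14.4 ± 1.94 in exa1 on MS, and 115 ± 1.85 and 12 ± 1.12 with NaCl. At 23 °C EXA1 was 134 ± 13.5 and 17 ± 0.944, and at 39 °C 89.3 ± 13.7 and 7.81 ± 0.605. The log2 fold change of EXA1 between genotypes was -2.71 ± 0.06 on MS (SE; adjusted p = 1.33e-97), -3.28 ± 0.06 with NaCl (adjusted p = 6.58e-110). It was -2.98 ± 0.11 at 23 °C (adjusted p = 5.57e-13) and -3.53 ± 0.12 at 39 °C (adjusted p = 1.67e-13). Remaining EXA1 reads do not show whether a functional transcript was left.

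Of the genes next to EXA1 on chromosome 5, the 4 that could be tested differed less than EXA1, and AT5G42955 and AT5G42957 had no reads in any library. In the order MS, NaCl, 23 °C and 39 °C, THO5 (AT5G42920) had log2 differences of 0.13 (adjusted p = 0.0392), 0.22 (7.7e-05), 0.28 (0.0292) and 0.18 (0.139), so it passed in 3 conditions. The THO5 call on MS was lost without WT_MS replicates 1 (adjusted p = 0.0651) and 3 (0.191) and exa1_MS replicates 1 (0.169) and 2 (0.0755), and with DESeq2 (0.0755), with no filter on low counts (0.0506) and with all 24 libraries in 1 fit (0.197). At 39 °C it passed with DESeq2 (0.0493) and with all 24 libraries in 1 fit (0.0208). At 23 °C it was lost without WT_23C replicates 1, 2 and 3 (0.0643, 0.0871 and 0.0966) and exa1_23C replicates 1, 2 and 3 (0.117, 0.0549 and 0.104). AT5G42930 had -0.54 (0.000104), -0.30 (0.00387; 0.0997 without WT_NaCl replicate 1 and 0.128 with all 24 libraries in 1 fit), 0.01 (0.998) and -0.29 (0.895). AT5G42940 had -0.15 (0.00441; 0.07 without WT_MS replicate 1 and 0.245 with all 24 libraries in 1 fit), -0.05 (0.419), -0.06 (0.819) and 0.09 (0.645). AT5G42960 passed in no condition, with -0.12 (0.254), -0.01 (0.922), -0.31 (0.0789) and -0.21 (0.184), but at 23 °C its exa1 libraries lay below those of the wild type (16.9 ± 1.56 against 21 ± 0.115 CPM), and it had adjusted p = 0.0174 with all 24 libraries in 1 fit and 0.0332 with only the 6 libraries compared.

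**Figure D1:**
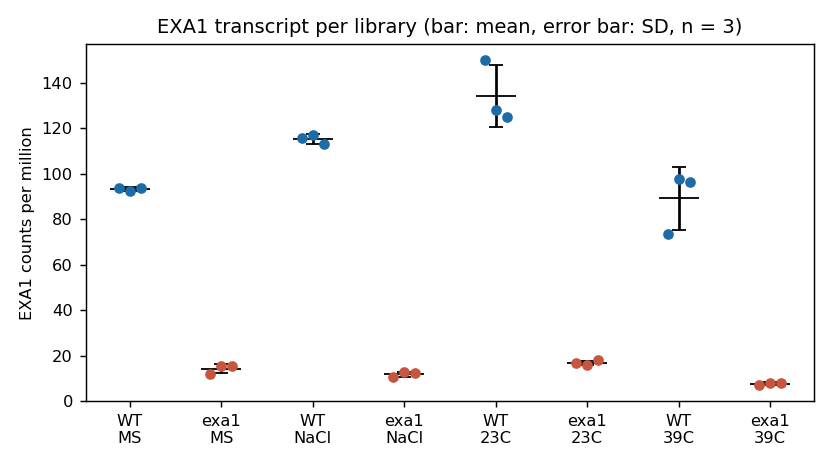
EXA1 in CPM of the library total (vertical axis) for each of the 24 libraries, grouped by genotype and condition. Every exa1 library lay below every wild-type library, for example 14.4 against 93.4 on average on MS.

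On MS, exa1 seedlings had lower transcript levels of auxin and growth genes, of light-harvesting genes and of salicylic acid defence genes, and higher levels of the defensin genes PDF1.2 and PDF1.3. IAA29 (AT4G32280), of the Aux/IAA family of auxin response repressors, was lower by log2 = -2.93 ± 0.18 (SE, n = 3 per genotype; adjusted p = 5.8e-35). The senescence-associated gene SAG13 was lower by -2.55 ± 0.16 (adjusted p = 1.56e-33), with all 3 exa1 libraries below all 3 wild-type libraries. ELI3-2 (-2.25 ± 0.10), the expansin gene EXPA8 (-2.17 ± 0.17) and GH3.3 (-2.03 ± 0.09), whose enzyme conjugates auxin, were also lower. The defensin genes PDF1.3 (AT2G26010; 4.25 ± 0.17, adjusted p = 1.02e-57) and PDF1.2 (AT5G44420; 4.17 ± 0.19, adjusted p = 3.38e-50) were higher in exa1, with MRD1 (4.19 ± 0.20), TZP (1.56 ± 0.05) and the aquaporin gene NLM1 (1.45 ± 0.15). Reads of PDF1.2, PDF1.2b, PDF1.2c and PDF1.3 may be exchanged between these near-identical genes, so it is uncertain which of them were higher.

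The auxin response and cell expansion list was lower in exa1 on MS for 22 of 23 genes (median log2 = -1.24, camera adjusted p = 2.58e-32), including IAA19 (-1.90 ± 0.11). Light-harvesting and carbon fixation genes, which serve photosynthesis, were lower for 21 of 23 (22 when adjusted over the list alone; median -0.585, adjusted p = 6.4e-56), including LHCB3 (-1.21 ± 0.04). Salicylic acid and defence genes were lower for 12 of 21 (12 over the list alone; median -0.74, adjusted p = 9.31e-07). Of these, PR2 was at -2.01 ± 0.19, PBS3 at -1.37 ± 0.17 and PR1 at -1.32 ± 0.06, but PR5 was higher (1.17 ± 0.12). Early stress transcription factors were lower for 16 of 23 (16 over the list alone; median -0.42, adjusted p = 5.03e-09), with WRKY40 at -0.88 ± 0.06. Jasmonate genes were lower for 17 of 24 (median -0.33, adjusted p = 5.85e-06), with VSP2 at -0.99 ± 0.08 and JAZ10 at -0.90 ± 0.07, though PDF1.2 of the same list was higher. Glucosinolate genes were lower for 11 of 14 (median -0.25, adjusted p = 7.61e-09), and ABA and drought genes for 14 of 24 (16 over the list alone; median -0.34, adjusted p = 9.31e-07), though COR15A was higher (1.11 ± 0.08). Plastid-encoded genes had a median of -0.41 (24 of 51 lower, 26 over the list alone; adjusted p = 0.000167). Root marker genes were higher for 6 of 16 (7 over the list alone; median 0.31, adjusted p = 0.00595), with NRT2.1 at 0.81 ± 0.06, but had adjusted p = 0.118 with an estimated correlation. The other 8 calls held with an estimated correlation, the highest adjusted p being 0.0477 for plastid-encoded genes.

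The listed genes of the translation machinery and of immune receptors, processes with which EXA1 has been linked, did not shift as groups on MS. The cytosolic ribosomal protein list held 28 genes found by words in the annotation, so it may cover only a part of the family. It had a median of -0.015 (1 of 24 higher and 4 lower, camera adjusted p = 0.879), with a median of 0.006 on FPKM values. At 23 °C its median was 0.163. Translation factor genes had a median of 0.008 (6 of 18 higher and 2 lower, 7 and 2 over the list alone; adjusted p = 0.102). Among them PAB4 was higher by 0.27 ± 0.03 (adjusted p = 9.14e-19) and GCN2 by 0.50 ± 0.05 (adjusted p = 1.44e-15). Of 19 NLR immune receptor genes 5 were higher and 7 lower (median -0.08, adjusted p = 0.856), such as RPP4 at 0.68 ± 0.06 and RPS2 at -0.90 ± 0.09. EIF4E1 (-0.01 ± 0.04, adjusted p = 0.903) and PAD4 (0.03 ± 0.11, adjusted p = 0.885) did not differ. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6385 of 21759 genes differed between genotypes on MS (2895 higher and 3490 lower), 508 of them by 2-fold or more. The higher share was 45.3%, but 51.4% on FPKM values and 34.3% of 2760 with all 24 libraries in 1 fit. In 41.4% of genes the libraries of the 2 genotypes did not overlap, against 10% by chance.

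With NaCl, exa1 seedlings had lower levels of light-harvesting and glucosinolate genes than the wild type, and slightly higher levels of ABA and drought genes. The cold- and ABA-responsive gene COR15A (AT2G42540) was higher by log2 = 1.31 ± 0.03 (SE, n = 3 per genotype; adjusted p = 5.81e-100). Also higher were the defensin genes PDF1.3 (2.97 ± 0.11), PDF1.2 (2.41 ± 0.12) and PDF1.2c (2.39 ± 0.16), which may exchange reads, and the thioredoxin gene TH8 (1.38 ± 0.10). The immune regulator gene ACD6 (-2.27 ± 0.12, adjusted p = 2.23e-40), NdhM (-2.21 ± 0.18), PR2 (-1.82 ± 0.14) and FMO1 (-1.59 ± 0.22), a gene of systemic acquired resistance, were lower. RBCS1B was lower by -1.78 ± 0.22, but its reads may belong to its near-identical RBCS relatives.

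All 23 light-harvesting genes were lower in exa1 with NaCl (median -0.81, camera adjusted p = 2.01e-98), with LHCB3 at -1.44 ± 0.04 (adjusted p = 6.7e-82). Glucosinolate genes were lower for 10 of 14 (median -0.74, adjusted p = 1.75e-10), with CYP79F1 (-1.13 ± 0.06), BCAT4 (-1.12 ± 0.05) and MAM1 (-1.11 ± 0.04), which act in methionine-derived glucosinolate synthesis. ABA and drought genes were higher for 18 of 24 (median 0.24, adjusted p = 2.64e-12), including RD29B (0.78 ± 0.08), RD29A (0.28 ± 0.02, adjusted p = 3.12e-34) and RAB18 (0.21 ± 0.03). Genes of the unfolded protein response, which encode chaperones of the endoplasmic reticulum, were higher for 10 of 16 (11 over the list alone; median 0.24, adjusted p = 9.51e-05), with CRT1 at 0.50 ± 0.03 and BIP2 at 0.40 ± 0.03 but BIP3 at -0.72 ± 0.19. Auxin genes were lower for 14 of 23 (median -0.44, adjusted p = 9.77e-05), with IAA29 at -1.75 ± 0.20, and jasmonate genes for 14 of 24 (median -0.21, adjusted p = 0.00223), with LOX2 at -0.87 ± 0.04. These 6 calls held with an estimated correlation (highest adjusted p = 0.023, for jasmonate). Salicylic acid and defence genes (10 of 21 lower, 11 over the list alone; median -0.44, adjusted p = 0.0101) had adjusted p = 0.0777 with an estimated correlation.

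Of the single marker genes, NCED3, which encodes the rate-limiting enzyme of ABA synthesis, was higher in exa1 with NaCl (log2 = 0.29 ± 0.05, adjusted p = 6.27e-07). The proline synthesis gene P5CS1 was lower (-0.51 ± 0.03, adjusted p = 5.79e-39) while P5CS2 was higher (0.63 ± 0.03). DREB2A was lower by -0.21 ± 0.04, and SOS1, which encodes a sodium exporter, did not differ (0.04 ± 0.08, adjusted p = 0.77). Sodium and potassium transport genes did not shift as a group (median 0.035, 3 of 15 higher and 2 lower; camera adjusted p = 0.762). With NaCl 7794 of 21759 genes differed between genotypes (4052 higher and 3742 lower), 504 by 2-fold or more. The higher share was 52%, but 57% on FPKM values and 38.6% of 4052 with all 24 libraries in 1 fit. With no filter on low counts it was 48.5%, and with only the 6 libraries compared 48%. It was 47.4, 47 and 47.7% without WT_NaCl replicates 1, 2 and 3 and 47.4% without exa1_NaCl replicate 3.

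At 23 °C, the unstressed condition of the heat set, exa1 seedlings again had higher transcripts of PDF1.2, PDF1.2b and PDF1.3, which may exchange reads, and lower levels of salicylic acid and auxin genes. PDF1.2b (AT2G26020) was higher by log2 = 4.13 ± 0.28 (SE, n = 3 per genotype; adjusted p = 1.69e-08), with PDF1.3 at 4.15 ± 0.37 and PDF1.2 at 3.39 ± 0.36. Also higher was the acyltransferase gene AACT1 (AT5G61160), at 1.53 ± 0.26 (adjusted p = 0.00304). PBS3, which acts in salicylic acid synthesis, was lower by -2.85 ± 0.29 (adjusted p = 5.02e-06), and the camalexin synthesis genes CYP71A12 (-2.81 ± 0.23, adjusted p = 2.52e-07) and PAD3 (-2.09 ± 0.20, adjusted p = 2.83e-06) were lower. PR2 was lower by -1.97 ± 0.29 and the defence transcription factor gene CBP60G by -1.37 ± 0.20. The cytosolic chaperone gene HSP70-2 was lower by -1.29 ± 0.13 (adjusted p = 4.27e-06), and PIF4, which encodes a growth regulator, by -0.86 ± 0.15. PR1 was -1.03 ± 0.32 (adjusted p = 0.0854), PAD4 -0.53 (adjusted p = 0.0792) and EIF4E1 -0.18 ± 0.10 (adjusted p = 0.297).

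Salicylic acid and defence genes were lower at 23 °C for 9 of 21 (14 over the list alone; median -1.03, camera adjusted p = 1.19e-15). Auxin genes were lower for 10 of 22 (12 over the list alone; median -0.47, adjusted p = 9.67e-12), with EXPA8 at -1.15 ± 0.17. Both calls held with an estimated correlation (adjusted p = 0.0206 for each). Light-harvesting genes (7 of 23 lower, 10 over the list alone; median -0.16, adjusted p = 0.000177) had adjusted p = 0.57 with an estimated correlation, with LHCB3 at -0.81 ± 0.11. Early stress transcription factors (6 of 18 lower, 11 over the list alone; median -0.52, adjusted p = 1.72e-06) and clock genes (4 of 16 lower; median -0.15, adjusted p = 0.00334) each had adjusted p = 0.148 with an estimated correlation. Of 21196 genes, 1598 differed between genotypes at 23 °C (695 higher and 903 lower), 306 by 2-fold or more. The count was 808 without WT_23C replicate 2, 959 without WT_23C replicate 3, 759 without exa1_23C replicate 1, 777 without exa1_23C replicate 2 and 1052 without exa1_23C replicate 3. It was 3216 with only the 6 libraries compared and 3924 with all 24 libraries in 1 fit. Counts on MS and at 23 °C are not comparable, since replicates varied more in the heat set. With all 24 libraries in 1 fit, 2760 genes differed on MS, fewer than at 23 °C.

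At 39 °C, exa1 seedlings had lower transcripts of several defence genes than the wild type, while the heat shock marker genes HSP101, HSP21, HSP90.1, HSFA2 and MBF1C did not differ. PR2 (AT3G57260), a glucanase gene induced in defence, was lower by log2 = -4.47 ± 0.43 (SE, n = 3 per genotype; adjusted p = 2.47e-06), TAT3 by -3.65 ± 0.56 (adjusted p = 0.000767) and NUDT6 by -3.22 ± 0.38 (adjusted p = 3.37e-05). XPL1 (AT3G18000), of choline synthesis, was lower by -2.84 ± 0.18 (adjusted p = 6.78e-09), and the defence genes WRKY70 by -2.32 ± 0.38 and FMO1 by -2.28 ± 0.27. MLO7 was higher by 2.93 ± 0.26 (adjusted p = 5.77e-07), PDF1.2b by 3.09 ± 0.29, PDF1.3 by 3.00 ± 0.38 and PDF1.2 by 2.62 ± 0.37. HSP101 (0.08 ± 0.09, adjusted p = 0.575), HSP21 (0.11 ± 0.08, adjusted p = 0.384), HSP90.1 (0.05 ± 0.10, adjusted p = 0.777), HSFA2 (-0.20 ± 0.11, adjusted p = 0.248) and MBF1C (-0.16 ± 0.15, adjusted p = 0.496) did not differ. HSP70-2 was again lower (-1.12 ± 0.10, adjusted p = 7.15e-07) and HSP90.6 was higher (0.63 ± 0.10).

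Salicylic acid and defence genes were lower at 39 °C for 13 of 21 (median -1.24, camera adjusted p = 6.61e-12; adjusted p = 0.0974 with an estimated correlation), with PAD4 at -1.07 ± 0.22. Light-harvesting genes were lower for 14 of 23 (18 over the list alone; median -0.39, adjusted p = 4.48e-15; adjusted p = 0.253 with an estimated correlation), with LHCB3 at -1.11 ± 0.11. Early stress transcription factors (5 of 18 lower; median -0.50, adjusted p = 0.000323) and auxin genes (6 of 22 lower, 8 over the list alone; median -0.51, adjusted p = 0.00183) each had adjusted p = 0.317 with an estimated correlation. Their members included ERF6 at -1.01 ± 0.14 and IAA19 at -1.51 ± 0.25. Small heat shock protein genes (0 of 6; median 0.09, adjusted p = 0.552) did not shift as a group. Nor did HSP70, HSP90, HSP100 and co-chaperone genes (5 of 20 higher and 2 lower, 7 and 2 over the list alone; median 0.12, adjusted p = 0.266) or heat shock factor genes (2 of 21 higher and 1 lower, 3 and 2 over the list alone; median 0.11, adjusted p = 0.668). Of 21196 genes, 3280 differed between genotypes at 39 °C (1579 higher and 1701 lower), 487 by 2-fold or more. The higher share was 48.1%, but 56.6% of 3515 with RLE size factors and 57% of 4008 with DESeq2. It was 50.7, 51 and 56.3% without WT_39C replicates 1, 2 and 3, and 55.2, 49.9 and 50.7% without exa1_39C replicates 1, 2 and 3. With all 24 libraries in 1 fit 5685 genes passed, 56.2% of them higher, and with only the 6 libraries compared 1854, 42% of them higher. The count was 2141 without WT_39C replicate 2 and 1741 without exa1_39C replicate 2.

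**Figure D2:**
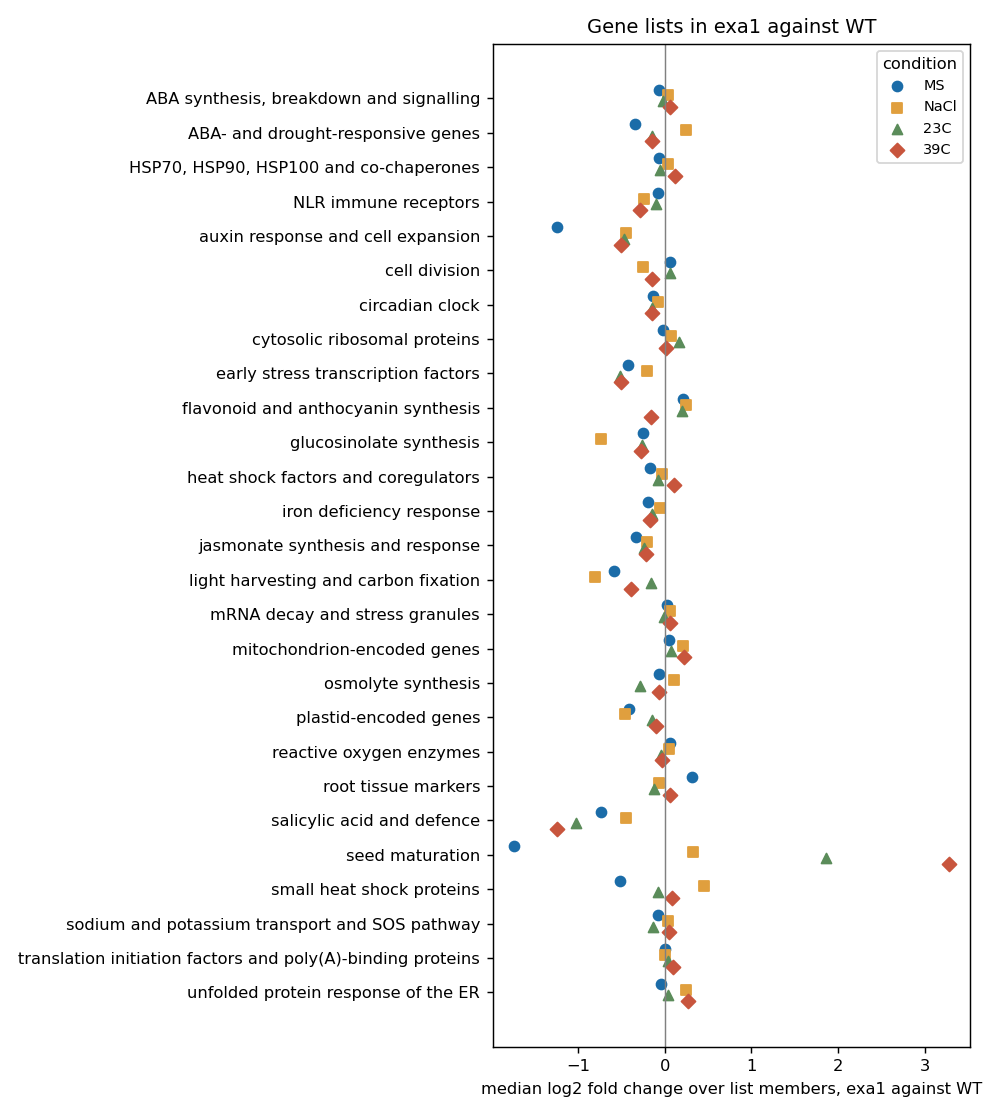
Median log2 fold change of exa1 over the wild type (horizontal axis) for the 27 gene lists in the 4 conditions, with n = 3 libraries per genotype. Compared between conditions within each list, auxin genes were lowest on MS (-1.24), salicylic acid and defence genes at 39 °C (-1.24) and light-harvesting genes with NaCl (-0.81).

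Genes that differed between genotypes in the unstressed condition of either set overlapped more than by chance. Of 20852 genes tested in both, 333 were higher in exa1 in both (94.8 by chance, Fisher's exact p = 6.43e-110) and 614 were lower in both (143.6 by chance, p = 7.48e-290), while 35 differed in opposite directions. The fold changes had a correlation of 0.542 across genes, and the 2 comparisons share no library. Fisher's test treats genes as independent, so its p-values do not measure the spread between samples. Of these 947 genes, 125 differed by at least 2-fold in both, such as IAA19, PR2 and PDF1.3. The number shared was 548 without WT_23C replicate 2, 616 without WT_23C replicate 3, 507 without exa1_23C replicate 1 and 541 without exa1_23C replicate 2. Under stress, 547 genes were higher in exa1 with both NaCl and 39 °C (298.6 by chance), 782 were lower in both (296.1 by chance) and 321 had opposite directions, with a correlation of 0.279.

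NaCl raised ABA, drought and jasmonate genes in both genotypes and lowered genes of the endoplasmic reticulum, of cell division and of roots. RD29A (AT5G52310), a gene induced by drought and ABA, rose by log2 = 4.57 ± 0.02 in the wild type (SE, n = 3 per condition; adjusted p = 1.2e-209) and by 4.94 ± 0.02 in exa1 (adjusted p = 3.14e-214). NCED3 rose by 4.63 ± 0.09 and 7.25 ± 0.11, RD29B by 6.80 ± 0.18 and 9.05 ± 0.19, RAB18 by 5.87 ± 0.06 and 6.36 ± 0.07, P5CS1 by 3.80 ± 0.04 and 3.33 ± 0.04, and DREB2A by 3.83 ± 0.05 and 3.78 ± 0.05. The largest rises in the wild type included BHLH92 (9.08 ± 0.19, adjusted p = 1.2e-101), TSPO (8.40 ± 0.17) and the late embryogenesis gene LEA4-5 (8.32 ± 0.08). In exa1 LEA4-5 rose by 10.07 ± 0.08, and MYB121 and LTP4, without reads in exa1 on MS, rose at least 269-fold and at least 229-fold. The receptor-like kinase gene CRK30 (-7.12 ± 0.19 and -8.29 ± 0.17), the ABA receptor gene PYL6 (-6.08 ± 0.11 and -6.90 ± 0.10) and the cell wall gene XTH33 (-5.95 ± 0.31 and -6.67 ± 0.34) fell most. SOS1 did not change in the wild type (0.06 ± 0.08, adjusted p = 0.506) or in exa1 (-0.03 ± 0.07, adjusted p = 0.714).

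All 24 ABA and drought genes rose with NaCl in both genotypes (median 3.59 in the wild type, camera adjusted p = 6.64e-66; 4.29 in exa1, adjusted p = 5.42e-58). Among them RD20 rose by 6.49 ± 0.07 and 6.79 ± 0.08. Genes of ABA synthesis, breakdown and signalling rose for 21 of 25 in both (1.92, adjusted p = 6.53e-12, and 2.23), including the phosphatase genes HAI1 (6.25 ± 0.06 and 7.72 ± 0.07) and HAI2 (7.90 ± 0.11 and 9.16 ± 0.14). Jasmonate genes rose for 23 of 24 in the wild type (median 1.52, adjusted p = 2.51e-16) and for 22 of 24 in exa1 (1.48). Early stress transcription factors rose for 22 of 23 in both (1.83, adjusted p = 3.98e-15, and 2.04), with MYB15 at 3.90 and 4.36. Heat shock factor genes rose for 18 of 21 in both (0.92, adjusted p = 1.78e-06, and 0.99), with HSFA6B at 7.24 ± 0.07 and 7.63 ± 0.07. Unfolded protein response genes fell for 10 of 16 in the wild type and 9 in exa1 (-1.06, adjusted p = 5.49e-07, and -0.64), with CRT1 at -1.93 ± 0.03 and -1.45 ± 0.03. Cell division genes fell for 13 of 16 and 15 of 16 (-0.84, adjusted p = 0.00522, and -1.10), with PCNA1 at -2.02 ± 0.10 and -2.28 ± 0.11. Root marker genes fell for 14 of 16 in both (-1.35, adjusted p = 0.000324, and -1.53), with PRP3 at -4.47 ± 0.15 and -4.93 ± 0.13. These calls held with an estimated correlation (highest adjusted p = 0.0446, root markers in the wild type). Light-harvesting genes rose for 18 of 23 in both genotypes (19 in the wild type over the list alone; 0.71, adjusted p = 1.94e-14, and 0.54, adjusted p = 3.73e-06), with LHCA2 at 1.22 ± 0.02 and 1.06 ± 0.02. With an estimated correlation they had adjusted p = 0.0103 in the wild type and adjusted p = 0.0599 in exa1. Sodium and potassium transport genes did not shift as a group (-0.09, adjusted p = 0.985, and 0.05, adjusted p = 0.83), though NHX1 rose by 1.31 ± 0.04 and 1.35 ± 0.04.

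With NaCl, 16199 genes changed in the wild type (8027 up and 8172 down; 4850 by 2-fold or more) and 16318 in exa1 (8079 and 8239; 5259 by 2-fold or more). Changes are relative to the rest of the transcriptome. On FPKM values scaled by totals, the median of all genes moved by -0.146 in the wild type and by -0.149 in exa1, and the share of changed genes that rose went from 49.6 to 38.4% and from 49.5 to 38.1%. With all 24 libraries in 1 fit that share was 54.2% in the wild type and 52.3% in exa1.

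ABA and drought genes rose more with NaCl in exa1, while auxin genes, which were lower in exa1 on MS, had a median change of -0.82 with NaCl in the wild type and of -0.20 in exa1. NAC019 rose by log2 = 1.65 ± 0.17 more in exa1 (SE, n = 3 per group; adjusted p = 4.35e-16), KIN1 by 1.15 ± 0.07 more and RD29A by 0.36 ± 0.03 more (adjusted p = 2.9e-24). Of the genes of ABA synthesis, breakdown and signalling, NCED3 rose by 2.62 ± 0.24 more (adjusted p = 1.24e-19) and HAI1 by 1.47 ± 0.17 more. That list did not shift as a group (median 0.09, mean 0.40; 7 of 25 more positive and 2 more negative, 9 and 3 over the list alone; camera adjusted p = 0.0579). For NCED3 the genotype difference with NaCl was far smaller than its interaction, most of which reflects a lower level in exa1 on MS. P5CS1 rose by 0.48 ± 0.06 less (-0.48, adjusted p = 7.88e-12), and DREB2A did not differ in its response (-0.05 ± 0.09, adjusted p = 0.782). The glutathione transferase gene GSTU3 (AT2G29470; 3.74 ± 0.30, adjusted p = 1.52e-23) went from 4.39 to 14.5 TMM-scaled CPM in the wild type and from 0.312 to 13.9 in exa1. NATA1, of acetylornithine synthesis, had an interaction of 3.65 ± 0.30 (adjusted p = 7.86e-23). Auxin genes GH3.3 (2.104 ± 0.104, adjusted p = 4.01e-41) and IAA19 (1.90 ± 0.14, adjusted p = 2e-26), the early genes WRKY40 (0.81 ± 0.07) and RAP2.6 (0.67 ± 0.04), and PR1 (1.49 ± 0.08, adjusted p = 6.22e-38) had more positive changes in exa1. Of these, GH3.3, IAA19, WRKY40 and PR1 started from lower levels in exa1 on MS, so their interactions do not show higher levels with NaCl.

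Of the ABA and drought list, 17 of 24 genes responded more in exa1 (19 over the list alone; median interaction 0.56, camera adjusted p = 3.47e-21). Auxin genes had a median of 0.50 (11 of 23 more positive; adjusted p = 1.47e-09) and unfolded protein response genes of 0.34 (12 of 16; adjusted p = 3.5e-10), with CRT1 at 0.48 ± 0.04. Light-harvesting and carbon fixation genes had a median of -0.29 (19 of 23 more negative, 21 over the list alone; adjusted p = 1.55e-20), and early stress transcription factors of 0.37 (10 of 23 more positive; adjusted p = 5.55e-05). These 5 calls held with an estimated correlation (highest adjusted p = 0.0248). Glucosinolate genes had a median of -0.385 (8 of 14 more negative and 4 more positive; adjusted p = 0.00483, and adjusted p = 0.0606 with an estimated correlation), with MYB28 at -0.91 ± 0.07 and MAM1 at -0.85 ± 0.06. In all, 4606 of 21759 genes responded differently between genotypes (2514 more positive and 2092 more negative), 442 by 2-fold or more. With all 24 libraries in 1 fit the count was 1612.

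Over all genes that changed in the wild type, the salt responses of exa1 had a slope of 1.09 on those of the wild type (correlation 0.945), with 95.3% of the same sign and 46.9% larger in exa1. Over genes that changed in exa1 the slope was 1.12 and the share 56.8%, so the share depends on how genes were picked.

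**Figure D3:**
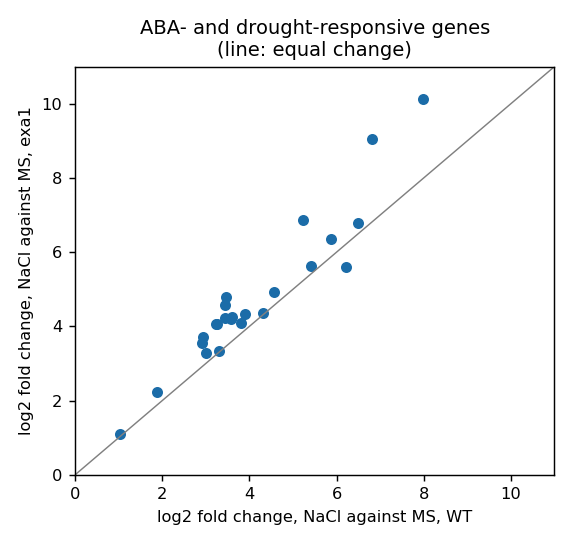
Response to NaCl (log2, NaCl over MS) of the 24 ABA and drought genes in the wild type (horizontal axis) and in exa1 (vertical axis), n = 3 libraries per group. The response was larger in exa1 for 23 of the 24 genes, for example RD29A (4.57 and 4.94).

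Heat at 39 °C raised heat shock protein genes by large factors in both genotypes. HSP101 (AT1G74310), which encodes a protein disaggregase, rose by log2 = 10.02 ± 0.13 in the wild type (SE, n = 3 per condition; adjusted p = 1.24e-22) and by 10.18 ± 0.13 in exa1 (adjusted p = 1.05e-22). HSFA2 rose by 12.95 ± 0.20 and 13.31 ± 0.21, HSP21 by 13.81 ± 0.17 and 13.60 ± 0.17, HSP90.1 by 10.06 ± 0.16 and 10.32 ± 0.16, MBF1C by 8.74 ± 0.21 and 8.83 ± 0.21, and HSP17.6II by 15.06 ± 0.24 and 15.37 ± 0.25. APX2, without reads in the wild type at 23 °C, rose at least 2440-fold there and by log2 = 11.52 ± 0.33 in exa1. The trans-acting siRNA gene TAS3 (-6.69 ± 0.31 and -5.59 ± 0.27), UCC2 (-5.55 ± 0.16 and -6.30 ± 0.18) and the ubiquitin ligase gene ATL8 (-5.67 ± 0.44 and -5.67 ± 0.46) fell most. All 20 HSP70, HSP90, HSP100 and co-chaperone genes rose (median 5.64 in the wild type, camera adjusted p = 1.42e-85; 5.95 in exa1, adjusted p = 1.53e-82), as did all 6 small heat shock protein genes (13.89, adjusted p = 1.12e-49, and 14.93). Heat shock factor genes rose for 14 of 21 in the wild type and 16 in exa1 (2.47, adjusted p = 2.52e-15, and 2.43). These calls held with an estimated correlation (highest adjusted p = 0.00856).

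Heat also raised genes of the endoplasmic reticulum, of the mitochondrial genome, of light harvesting and of ABA and drought, and lowered glucosinolate and auxin genes. None of these 6 list calls held with an estimated correlation: in the wild type and exa1, unfolded protein response adjusted p = 0.134 and 0.128, mitochondrion 0.385 and 0.416, light harvesting 0.108 and 0.128, ABA 0.0935 and 0.128, glucosinolate 0.123 and 0.128, auxin 0.167 and 0.329. Unfolded protein response genes rose for 13 of 16 in the wild type and 12 in exa1 (median 2.27, adjusted p = 6.49e-12, and 2.65), with ERDJ3A at 8.18 ± 0.13 and 8.93 ± 0.14 and BIP1 at 4.18 ± 0.10 and 4.39 ± 0.10. All 24 mitochondrion-encoded genes rose (3.99, adjusted p = 6.29e-05, and 4.18), with cox1 at 4.96 ± 0.21 and 5.08 ± 0.20. The mitochondrial share of reads was 0.019% at 23 °C and 0.0943% at 39 °C in the wild type, and 0.0213% and 0.108% in exa1. The share of ribosomal RNA reads moved alike, from 0.0311 to 0.0323% at 23 °C to 0.0843 to 0.1012% at 39 °C in wild-type libraries and from 0.0289 to 0.0297% to 0.0861 to 0.1183% in exa1 libraries. The replicate with the highest share of both was exa1_39C replicate 2, and a change in RNA or library quality with heat was not tested. Light-harvesting genes rose for 21 of 23 and 23 of 23 (2.05, adjusted p = 1.27e-15, and 1.98), with LHCB1.1 at 6.13 and 5.73, although LHCB1 reads may be exchanged between its close relatives. ABA and drought genes rose for 17 of 24 and 16 of 24 (1.70, adjusted p = 2.2e-06, and 1.935), with RD29A at 5.38 ± 0.19 and 5.07 ± 0.18. Glucosinolate genes fell for 12 of 14 in both (-1.66, adjusted p = 6.28e-06, and -1.40), with MYB28 at -4.08 ± 0.15 and -3.60 ± 0.14. Auxin genes fell for 17 of 22 and 14 of 22 (-1.51, adjusted p = 0.0068, and -1.73), with EXPA1 at -4.90 ± 0.17 and -4.63 ± 0.17.

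At 39 °C, 15929 genes changed in the wild type (7752 up and 8177 down; 8457 by 2-fold or more) and 16096 in exa1 (7685 and 8411; 8814 by 2-fold or more). The direction of moderate changes depends on scaling, with TMM factors of 1.3428 to 1.3915 at 23 °C and of 0.7211 to 0.7433 at 39 °C in the wild type. On FPKM values scaled by totals, the median of all genes moved by -0.831 in the wild type and by -0.809 in exa1, and the share of changed genes that rose went from 48.7 to 14.8% and from 47.7 to 16.5%. EXA1 itself rose at 39 °C in the wild type by 0.31 (adjusted p = 0.00877) but fell on FPKM values (-0.567, adjusted p = 0.000274). The call was lost without WT_23C replicate 3 (adjusted p = 0.0525) or WT_39C replicate 2 (adjusted p = 0.0776), with a range of 0.000332 to 0.0776 over the alternatives that gave a rise.

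For the heat shock marker genes given here, no difference between genotypes in the response to heat was detected. On simulated counts, only 16.4% of heat interactions of log2 = 0.5 were recovered. HSP101 (log2 interaction 0.16 ± 0.14, SE, n = 3 per group; adjusted p = 0.6), HSFA2 (0.37 ± 0.31, adjusted p = 0.577), HSP90.1 (0.25 ± 0.16, adjusted p = 0.448) and HSP21 (-0.22 ± 0.48, adjusted p = 0.876) did not pass. XPL1, of choline synthesis, had an interaction of -2.42 ± 0.22 (adjusted p = 1.64e-05). In TMM-scaled CPM, a unit unlike that of EXA1 above, XPL1 went from 49.6 to 25.2 in the wild type and from 37 to 3.52 in exa1. GOLS1, of raffinose synthesis, had 0.76 ± 0.12 (adjusted p = 0.00369), the DNA repair gene XRCC3 1.67 ± 0.32 (adjusted p = 0.0135), and the ABA receptor gene PYL4 -0.64 ± 0.12 (adjusted p = 0.0126). Over genes that changed in the wild type, the heat responses of exa1 had a slope of 1.026 on those of the wild type, with 98.2% of the same sign and 49.3% larger in exa1. Over genes that changed in exa1 the slope was 1.055 and the share 58.3%.

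In all, 347 of 21196 genes responded differently to heat between genotypes (180 more positive and 167 more negative), 94 by 2-fold or more, such as XPL1. The higher share was 51.9%, but 63.1% with RLE size factors and 61.2% with DESeq2. It was 48.5% without WT_23C replicate 2, and 47.7 and 49.4% without exa1_23C replicates 1 and 2. With any other library left out it was 50.4 to 65.9%. DESeq2 gave 885 genes, all 24 libraries in 1 fit 2154, and FPKM values 137. Counts for heat and for salt are not comparable, since replicates varied more in the heat set. The biological coefficient of variation was 0.0964 in the heat fit and 0.0309 in the salt fit. With all 24 libraries in 1 fit the salt interaction gave 1612 genes, fewer than heat. The count was 99 without WT_23C replicate 2, 158 without WT_23C replicate 3, 129 without WT_39C replicate 2 and 1481 without WT_39C replicate 3. It was 109, 85 and 128 without exa1_23C replicates 1, 2 and 3, and 610, 155 and 151 without exa1_39C replicates 1, 2 and 3.

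The unstressed groups of the 2 sets, both described as grown for 9 days, differed in most genes. ASN1 (AT3G47340), an asparagine synthetase gene induced by darkness and low sugar, was higher at 23 °C than on MS by log2 = 5.66 ± 0.20 in the wild type (SE, n = 3 per group; adjusted p = 7.16e-09) and 5.49 ± 0.21 in exa1. SEN1 (AT4G35770), also induced by darkness, was higher by 4.75 ± 0.16 (adjusted p = 3.29e-09) and 4.78 ± 0.16, and the ferric reductase gene FRO6 by 5.44 ± 0.35 and 5.86 ± 0.37. KIN1, a cold- and drought-induced gene, was lower by -6.40 ± 0.25 (adjusted p = 1.25e-14) and -5.11 ± 0.26, DIR5 by -6.21 ± 0.33 and -5.86 ± 0.34, and the ribonuclease gene RNS1 by -4.95 ± 0.24 and -5.57 ± 0.29. All 23 light-harvesting genes were higher at 23 °C in both genotypes (median 1.44, camera adjusted p = 4.16e-23, and 1.76), with LHCA4 at 2.38 ± 0.06 and 2.50 ± 0.06. Chaperone genes were lower for 18 of 20 in the wild type and 17 in exa1 (-1.11, adjusted p = 4.28e-15, and -1.30), with HSP90.1 at -2.89 ± 0.08 and -2.70 ± 0.08. Both calls held with an estimated correlation (highest adjusted p = 0.0122). Unfolded protein response genes were lower for 14 of 16 in both (15 in the wild type over the list alone; -1.42, adjusted p = 1.24e-12, and -1.21). Jasmonate genes were lower for 17 of 23 and 18 of 23 (-0.98, adjusted p = 1.35e-05, and -0.86) and glucosinolate genes for 13 of 14 and 11 of 14 (-1.01, adjusted p = 2.98e-08, and -0.805). With an estimated correlation these had adjusted p = 0.04 each in the wild type, and adjusted p = 0.104, 0.108 and 0.104 in exa1.

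Between the unstressed groups, 14427 genes differed in the wild type (7240 higher at 23 °C and 7187 lower; 4125 by 2-fold or more) and 14552 in exa1 (7265 and 7287; 4269 by 2-fold or more). On FPKM values the median of all genes moved by -0.215 and -0.246, and the higher share went from 50.2 to 33.4% and from 49.9 to 31.7%. The set is confounded with everything else that differed between the 2 experiments. How the genotype difference changed between the unstressed groups was tested after the data were seen, and 1559 of 21529 genes differed (1015 more positive at 23 °C and 544 more negative; 153 by 2-fold or more). GH3.3 (1.59 ± 0.27, adjusted p = 0.00194) and RTFL21 (2.15 ± 0.34, adjusted p = 0.000164) had a more positive genotype difference at 23 °C. PR5 (-1.64 ± 0.21, adjusted p = 1.08e-05) and NLM1 (-1.54 ± 0.15, adjusted p = 2.95e-07) had a more negative one. The count was 986 and 984 without WT_MS replicates 2 and 3, and 968, 954 and 962 without exa1_MS replicates 1, 2 and 3. It was 682 with all 24 libraries in 1 fit and 2292 without WT_23C replicate 1.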

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

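The results here are differences between genotypes in a response, or between the unstressed groups in the genotype difference, tested as interactions with n = 3 libraries per group. The tests of root markers, of the spread of the 23 °C libraries, of library parts and of the ABA gene level with NaCl, and the whole comparison of the genotype difference between the unstressed groups, were chosen after the results were seen.

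The salt response differed between genotypes for 4606 genes. Of 60 regroupings of the 12 libraries, 2 gave as many genes, the real one included. The other of the 2 gave 8777 by exchanging the genotypes in 1 condition, which turns the genotype difference into an interaction and so points to the structure of the samples, and the next highest gave 2589. Most regroupings mix genotypes within a condition, which adds the genotype difference to the spread and lowers the count (median 0). The regroupings therefore cannot exclude chance. The list medians of the difference were 0.556 for ABA and drought genes, 0.496 for auxin genes, 0.373 for early stress transcription factors, 0.34 for the unfolded protein response and -0.293 for light harvesting. They were -0.385 for glucosinolate genes (camera adjusted p = 0.00483), -0.359 for cell division (0.0115), 0.126 for chaperones (0.00108), 1.045 for 5 small heat shock protein genes (0.0031) and 0.295 for salicylic acid and defence genes (0.0124). With an estimated correlation these last 5 had adjusted p = 0.0606, 0.0615, 0.0989, 0.128 and 0.0989. The salicylic acid list had adjusted p = 0.053 with all 24 libraries in 1 fit.

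The genes with the most positive salt interaction were FLP1 (5.962), LTP4 (5.259), GSTU3 (3.736), NATA1 (3.648) and PRX52 (2.783). FLP1 and LTP4 had no reads in exa1 on MS, so their fitted values depend on the prior count and are no bounds. LTP4 had adjusted p = 0.0561 on FPKM values and 0.146 with all 24 libraries in 1 fit, in a range of 0.000162 to 0.146 over the alternatives. The most negative were MRD1 (-3.356), UMAMIT4 (-2.748), PDF1.2c (-2.262), GLIP2 (-1.89) and PDF1.2 (-1.764), where the defensin genes may exchange reads. With all 24 libraries in 1 fit, MRD1 (adjusted p = 0.244, lowest over the alternatives 3.16e-14), PDF1.2c (0.0896, lowest 5.88e-06) and PDF1.2 (0.077, lowest 6.13e-10) no longer passed. UMAMIT4 had adjusted p = 0.087 without WT_NaCl replicate 1 and 0.0586 without exa1_NaCl replicate 1 (lowest 0.00594). GLIP2 had adjusted p = 0.0539 and 0.0584 without WT_MS replicates 1 and 2, 0.0712, 0.123 and 0.0579 without WT_NaCl replicates 1, 2 and 3. It had 0.0674 without exa1_MS replicate 3, 0.0992 and 0.0656 without exa1_NaCl replicates 1 and 2, and 0.0516 with no filter on low counts (lowest 0.00059).

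The heat response differed between genotypes for 347 genes, and 3 of 60 regroupings gave as many, the real one included, so chance cannot be excluded. As replicates varied more in the heat set, this count is not comparable with that for salt. The highest count, 4203, again came from exchanging the genotypes in 1 condition and points to the structure of the samples, and the next was 568. The count was 99 and 158 without WT_23C replicates 2 and 3, 129 and 1481 without WT_39C replicates 2 and 3, 109, 85 and 128 without exa1_23C replicates 1, 2 and 3, and 610, 155 and 151 without exa1_39C replicates 1, 2 and 3. Chaperone genes had a median difference of 0.191 (camera adjusted p = 0.0472, and adjusted p = 0.813 with an estimated correlation) and light-harvesting genes of -0.252 (0.000202, and adjusted p = 0.836 with an estimated correlation). The chaperone call was lost without WT_23C replicate 3 (adjusted p = 0.0804), WT_39C replicates 2 (0.0584) and 3 (0.134), exa1_23C replicates 1 (0.0606) and 2 (0.0619) and exa1_39C replicate 1 (0.104), with a lowest value of 0.00246.

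The genes with the most positive heat interaction were RLP21 (4.979), MLO7 (2.265), XRCC3 (1.665), BGLU33 (1.387) and ABCC7 (1.324), and the most negative MAKR6 (-3.25), NUDT6 (-2.528), PR2 (-2.506), XPL1 (-2.415) and HB30 (-1.502). RLP21 had no reads in exa1 at 23 °C, so its value is no bound. MLO7, XRCC3, XPL1 and HB30 passed with each library left out, but on FPKM values MLO7 had adjusted p = 0.0579 (lowest over the alternatives 5.27e-07) and HB30 0.066 (lowest 2.97e-05). RLP21 had adjusted p = 0.0587, 0.0587 and 0.0855 without WT_23C replicates 1, 2 and 3, 0.0644 without WT_39C replicate 2, 0.0907, 0.104 and 0.0874 without exa1_23C replicates 1, 2 and 3, 0.0527 without exa1_39C replicate 2 and 0.399 on FPKM values (lowest 0.0103). BGLU33 had 0.0501 without WT_23C replicate 2 and 0.0516 and 0.0579 without exa1_23C replicates 1 and 2 (lowest 0.000938). ABCC7 had 0.118 and 0.0555 without WT_23C replicates 2 and 3, 0.0631 and 0.0634 without WT_39C replicates 1 and 2, 0.0768, 0.0949 and 0.0963 without exa1_23C replicates 1, 2 and 3, and 0.082 without exa1_39C replicate 3 (lowest 0.000948). MAKR6 had 0.0531 without WT_39C replicate 1, 0.051 without exa1_23C replicate 2, 0.0654 without exa1_39C replicate 3 and 0.282 on FPKM values (lowest 0.00101). NUDT6 had 0.0501 without WT_23C replicate 2, 0.0579 without exa1_23C replicate 2, 0.0527 and 0.0553 without exa1_39C replicates 2 and 3 and 0.066 on FPKM values (lowest 0.000152). PR2 had 0.0713 and 0.0684 without WT_23C replicates 2 and 3, 0.0506 without WT_39C replicate 1, 0.0823 and 0.105 without exa1_23C replicates 1 and 2, 0.0609, 0.0921 and 0.0711 without exa1_39C replicates 1, 2 and 3 and 0.473 on FPKM values (lowest 0.00295).

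The genotype difference itself differed between the unstressed groups for 1559 genes, and 2 of 60 regroupings gave as many, the real one included. The other gave 6709 by exchanging the genotypes in 1 group, which points to the structure of the samples, and the next gave 1246. As for salt, regroupings that mix genotypes have a larger spread, so they cannot exclude chance. The count was 986 and 984 without WT_MS replicates 2 and 3 and 968, 954 and 962 without exa1_MS replicates 1, 2 and 3. It was 682 with all 24 libraries in 1 fit and 2292 without WT_23C replicate 1. For comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05, and only the real split (1 of 10) gave as many genes in each. The real value and the highest other were 6385 and 0 between genotypes on MS, 7794 and 0 with NaCl, 1598 and 1 at 23 °C and 3280 and 344 at 39 °C. They were 16199 and 0 and 16318 and 0 for NaCl, 15929 and 0 and 16096 and 0 for heat, and 14427 and 0 and 14552 and 0 between the unstressed groups, in the wild type and exa1.

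A first pattern weighed was that the 2 unstressed groups differed in most genes. A smaller share of root tissue at 23 °C would lower root markers. Their median change was -0.091 in the wild type (95% interval -0.296 to 0.049) and -0.441 in exa1 (-0.624 to -0.205). The same markers also fell with NaCl (median -1.35 in the wild type and -1.526 in exa1), so their level can change with treatment. Such regulation was not separated from the share of root tissue, so this test cannot decide. Lower sugar status of the 23 °C seedlings is a candidate explanation, since 12 sugar-starvation genes had a median of 2.083 (1.091 to 2.716) in the wild type and 2.091 in exa1, with ASN1 and SEN1, which prompted the idea, left out. These genes also respond to darkness, which was not separated. Another harvest time stays open, since morning minus evening clock genes changed by 0.873 in the wild type and 1.416 in exa1 and the labels give no hour.

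A further pattern was that replicates varied more in the heat set, with a biological coefficient of variation of 0.0288 on MS and 0.033 with NaCl but 0.0782 at 23 °C and 0.114 at 39 °C. Depth was argued against, since after thinning all libraries to 17600922 reads the heat set still had 3.125 times the coefficient of the salt set. The heat treatment alone was argued against by the 23 °C libraries, with 2.72 times the coefficient of MS. Salt-set replicates as parts of 1 library were argued against, since their lowest chi-square per gene was 1.68, above the value of 1 that sampling alone gives. Separate libraries made from shared plant material could also exceed 1, so this value does not tell whether plants were pooled. Handling and growth conditions of the 2 sets stay open and were not tested.

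The last pattern was that ABA and drought genes rose more with NaCl in exa1. A lower level in unstressed exa1 (median -0.342) as the whole cause was argued against by their higher level in exa1 with NaCl (median 0.24, 0.134 to 0.295). Intervals in this paragraph were drawn over genes and do not measure the spread between libraries. A single library was argued against, since 15 to 18 of 24 genes had a positive interaction that passed with each library left out, the lowest number being without exa1_MS replicate 3. A larger salt response in exa1 in general stays open. The slope over the list (1.218) exceeded that over other genes (1.088) by 0.13, with an interval of -0.153 to 0.278. A slope does not register an extra rise that is equal for all genes of the list, so this test cannot decide. A biological effect of the exa1-1 genotype on these genes beyond that stays untested.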

How the results depend on the processing

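The alternatives for the genotype difference between the unstressed groups, and the response slopes over genes with at least 5 CPM and with a prior count of 2, were chosen after seeing the data. Over all alternatives, 4711 list tests kept their direction and side of the threshold, 145 became weaker and 86 stronger. For named genes the numbers were 17686, 1033 and 20, with 17 reversed, and for counts or slopes 187 were alike and 62 moved. The cause was not tested, except where fewer libraries leave less power.

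All 17 reversals arose on FPKM values scaled by totals, where the median of all genes moves. With NaCl in the wild type AT1G24300 was -0.00015. At 39 °C in the wild type AT5G57060 was -0.041, PFL -0.096, AT1G27430 -0.238, EXA1 -0.567, TT5 -0.019, FLS1 -0.356 and ERD5 -0.325, and in exa1 PFL was -0.131, AT1G27430 -0.02, P40 -0.266, TT4 -0.171 and SIP2 -0.421. Between the unstressed groups AT1G24300 was -0.024 in the wild type and -0.065 in exa1 and MAD2 -0.014 in exa1. JRG21 had 0.263 in the genotype difference, where the median moved by -0.033, so that shift does not account for its reversal.

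For the heat interaction, limma on FPKM values gave 137 genes and DESeq2 885. With all 24 libraries in 1 fit, the genotype difference gave 2760 genes on MS, 4052 with NaCl, 3924 at 23 °C and 5685 at 39 °C, the salt interaction 1612, the heat interaction 2154 and the genotype difference between unstressed groups 682. This fit estimates 1 dispersion per gene over both sets. With only the 6 libraries compared, 3216 genes passed at 23 °C and 1854 at 39 °C. The slope of exa1 on wild-type responses was 1.12 for salt and 1.055 for heat over genes that changed in exa1, 1.103 and 1.04 over genes that changed in both, 1.08 for salt with a prior count of 2 and 1.05 for heat at 5 CPM. The overlap of unstressed genotype differences was 125 at 2-fold.

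Leaving out 1 library gave, from lowest to highest, 5277 to 5619 genes between genotypes on MS, 6735 to 7010 with NaCl, 759 to 1319 at 23 °C and 1741 to 4505 at 39 °C. It gave 15506 to 15733 for NaCl in the wild type and 15735 to 15879 in exa1, and 15209 to 15630 and 15363 to 15598 for heat. It gave 13685 to 14255 and 13772 to 14008 between unstressed groups, 4114 to 4343 for the salt interaction, 85 to 1481 for the heat interaction, and 954 to 2292 for the genotype difference between unstressed groups. Slopes were 1.068 to 1.11 for salt and 0.99 to 1.05 for heat, and the overlap 507 to 899.

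Replicate numbers were not shown to pair libraries, since 0 of 18 salt and 1 of 18 heat pairs with the same number had a residual correlation above 0.1. Across numbers, WT_39C replicate 3 had 0.465 with exa1_39C replicate 2 and -0.388 with exa1_39C replicate 1, and WT_39C replicate 1 had -0.418 with exa1_39C replicate 2. WT_39C replicate 3 and exa1_39C replicate 2 also had the highest mitochondrial shares of their groups, and the cause was not tested. With the number as a block, 6283, 7707, 1486 and 3245 genes differed between genotypes on MS, with NaCl, at 23 °C and at 39 °C, and 4525 and 299 for the salt and heat interactions. At the depth of these libraries, genes without reads in a group gave only lower bounds, and genes with fewer reads than the filter asks were not tested.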

Other observations

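No hypothesis beyond those above was tested, and the genes here were chosen after their values were seen. The seed storage protein gene CRA1 was higher in exa1 than in the wild type at 39 °C (log2 = 4.989 ± 1.201, adjusted p = 0.0214, n = 3 per genotype), at 8.55 against 0.256 TMM-scaled CPM. The call was lost without WT_39C replicates 1 (adjusted p = 0.0767), 2 (0.0698) or 3 (0.0696), with a lowest adjusted p of 0.000132 over the alternatives. CRU3, another storage protein gene, had 4.76 (adjusted p = 0.061). On MS both were lower in exa1, CRA1 by -1.34 (adjusted p = 0.000889) and CRU3 by -2.12 (adjusted p = 4.91e-05), at under 2 CPM. The seed maturation list did not shift as a group between genotypes in any condition, with medians of -1.73 on MS (4 genes; camera adjusted p = 0.15), 0.33 with NaCl (4 genes; 0.506), 1.86 at 23 °C (6 genes; 0.121) and 3.27 at 39 °C (6 genes; 0.133). Most of its members had few reads, so these medians depend on the prior count and are no bounds.

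Of the sugar-starvation genes, the wild type had higher levels at 23 °C than on MS of MCCA (log2 = 3.90), BCAT-2 (3.87), DIN4 (3.14), DIN10 (2.29), TPS11 (2.23), BCE2 (2.19) and TPS8 (1.98), while DIN11 had -1.49 and EXL2 -0.51.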
